A study of Arabidopsis thaliana with 6 samples.

How the data were processed

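Seedlings of Arabidopsis thaliana Columbia-0 were grown in liquid medium in multiwell plates, given H2O2 to 10 mM or water at day 7, and harvested after 24 h. Per the labels' protocols, each replicate was leaf material pooled from 4 to 5 plants, while the labels give the source as seedling, and biotin-labelled cRNA was made by the standard Affymetrix procedure. The deposited values are log2 GCRMA values per the submitters' processing notes (GCRMA corrects background by probe sequence, normalizes between arrays and summarises probes). The log2 scale was read from the values, which run from 1.55 to 13.2. The GCRMA version, chip type and probe definition are not given in the sources used here. Such values compress low signals toward a floor, so folds against a low group are uncertain, and normalization between arrays removes any overall difference in RNA content.

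The table held 21430 probe sets, each named by a different locus, with no hybridisation control probe sets, so the planned test of RNA integrity could not be made. Gene symbols came from a RefSeq gene table of assembly TAIR10.1, used for names only, in which 21231 loci were found and 199 were not. A group of 221 loci in 106 sets had identical values on all arrays, and these cannot be told apart. No 2 arrays held identical values.

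Groups were taken from the labels, with 3 mock and 3 H2O2 arrays. Probe sets with a mean over the 6 arrays under the 30th percentile (3.79 on the log2 scale) were left out, which removed 6429 and kept 15001. Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, H2O2 minus mock), with Benjamini-Hochberg adjustment and a threshold of 0.05. The residual degrees of freedom were 4 and the prior ones 4.30, and the median residual SD was 0.11. The arrays were compared by principal components and correlation. Gene lists were tested with camera at a preset correlation of 0.01, two-sided, with adjustment over all 34 lists with at least 5 measured genes. An estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, were alternatives. Figures were drawn with matplotlib 3.10.9.

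The groups, lists, tests and most alternatives were fixed before the data were examined. The genes named were, by a rule fixed then, the 12 with the largest increase and the 12 with the largest decrease among named genes that passed and whose groups did not overlap, up to 4 members of each list with the largest changes among those that passed (or the 1 with the largest change where none did), and the catalases, ascorbate peroxidases, superoxide dismutases and reference genes as values. Of the genes taken by this rule, 1 is not reported here. List members were matched by locus, or by symbol where the reference table gives the symbol to another locus. By these rules 8 members entered lists although they are known as other proteins, and the lists were also tested without them.

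The labels number the replicates alike in both groups. Deviations from the group means correlated across probe sets at 0.19, 0.21 and 0.21 for arrays of the same number and below 0 for all other pairs. Centring within each group pushes the other pairs below 0 when same-numbered pairs lie above it. The negative values thus add no support. Matching by number was the best of 6 possible ways, too few to decide whether the numbers pair the samples. A fit with the number as a block was therefore made as an alternative.

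Alternatives were no filter or a filter at the 50th percentile, low values raised to the 30th percentile, quantile normalization, centring on the median or on the reference genes, a trended and robust prior, no variance moderation, array weights, the replicate block, and each array left out in turn. Leaving out shared probe sets by their suffix, other probe sets of a gene and means over probe sets were not run, since each locus has 1 probe set.

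The scripts were tested on simulated data with the mock means of the 15001 probe sets, their residual spreads shuffled over probe sets, and 200 changed genes. For H2O2 against mock, 47.0% of genes changed by 0.5 on the log2 scale were recovered, 88.1% of those changed by 1 and 100% of those changed by 2. Of 161 calls, 4 were false. In the data 9066 probe sets were called, and the adjustment is less strict when more change, so these rates do not carry over to the data. The simulation also held no offset between arrays. Of 34 simulated lists, the 1 shifted list was called and none of the 33 others, in a simulation without correlation between genes.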

Results

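Transcript levels were measured in Arabidopsis thaliana Columbia-0 seedlings that had grown for 7 days in liquid medium and then spent 24 h with 10 mM hydrogen peroxide (H2O2), a reactive oxygen species, or with the same volume of water (mock). Each group had 3 replicates, each a pool from 4 to 5 plants hybridised to its own Affymetrix array. The labels disagree on what was pooled, giving leaf as the tissue and seedling as the source. Root genes were measured in mock, with PYK10, XTH14, PRP3 and CASP1 at 12.02, 8.86, 8.53 and 8.04 on the log2 scale. CASP4 and MRN1 were lower, at 4.28 and 3.95. These values argue against pools of leaf alone, but it is uncertain in what shares the values describe each organ. The table held 21430 probe sets, each for a different locus, as log2 GCRMA values. The median log2 value lay between 5.66 and 5.74 on all 6 arrays, and the number of arrays limits the precision of every value. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these pools, which may be partly technical.

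The comparison of H2O2 with mock asks which transcripts differ after 24 h of oxidative treatment. Genes of small heat shock proteins, which keep unfolding proteins soluble, were among those with the largest increases, led by HSP17.6A (AT5G12030), at 2.73 ± 0.18 in mock and 11.80 ± 0.11 in H2O2 (log2, SD, n = 3 each). HSP70 (AT3G12580), a chaperone gene, rose 132-fold (log2 change 7.05, SE 0.13), and the gene of the heat shock factor HSFA2 (AT2G26150) rose by 6.22 on the log2 scale (SE 0.11). Genes of cell expansion and of cytokinin signalling were among those with the largest decreases. The xyloglucan endotransglucosylase gene XTH33 (AT1G10550) was 6.41-fold lower (SE 0.16 log2) and the response regulator gene RR16 (AT2G40670) 6.16-fold lower (SE 0.27 log2).

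Of 15001 probe sets tested, 9066 (60.4%) changed at an adjusted p under 0.05 in limma, of which 3584 were higher and 5482 lower in H2O2. At least 2-fold changes were found for 1766 probe sets (11.8%), of which 1145 were higher and 621 lower. Higher probe sets thus made up 39.5% of all changes but 64.8% of those of at least 2-fold. With each array centred on 8 reference genes, which moved the median of all probe sets by 0.12 on the log2 scale, 4549 were higher and 3720 lower (55.0% higher), and among changes of at least 2-fold 1321 were higher and 443 lower (74.9% higher). The direction of the majority among all changes therefore depended on the scaling. The 3 arrays of one group lay beyond all 3 of the other for 10088 probe sets (67.2%), where chance gives 10%.

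**Figure D1:**
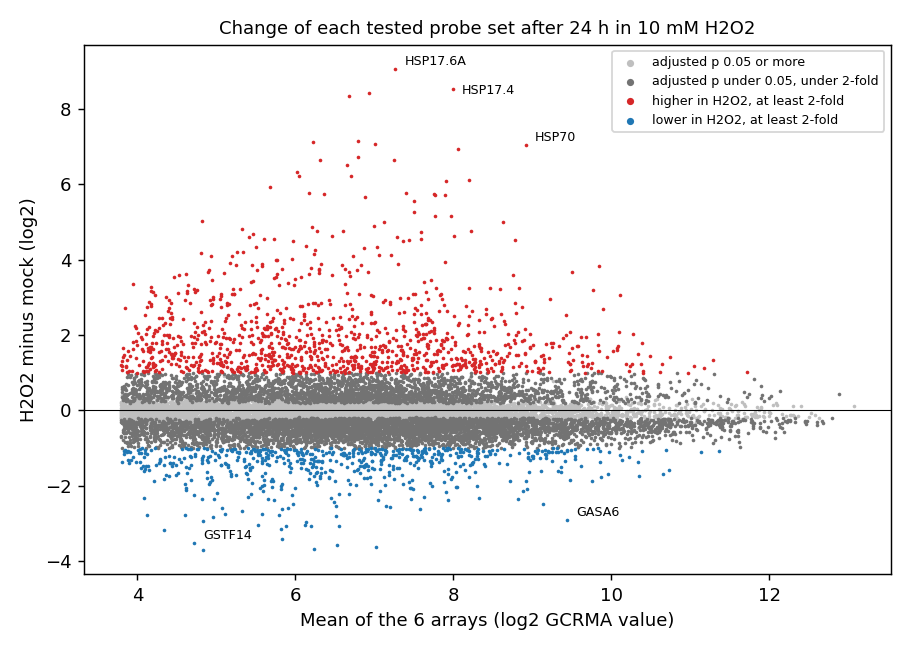
Each point is a tested probe set, with the mean of the 6 arrays (log2 GCRMA value) on the horizontal axis and the difference H2O2 minus mock (log2) on the vertical axis. Red and blue points are the 1145 higher and 621 lower probe sets that changed at least 2-fold at an adjusted p under 0.05.

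The first principal component held 91.3% of the variance between arrays and parted the mock arrays from the H2O2 arrays. Pearson correlations across probe sets, which are not independent replicates, were 0.991 to 0.995 within groups and 0.883 to 0.902 between them.

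The 12 named genes with the largest increases included 4 chaperone or small heat shock protein genes besides HSP17.6A and HSP70, namely HSP17.4 (AT3G46230), HSP17.6II (AT5G12020), HSP90.1 (AT5G52640) and HSP23.6-MITO (AT4G25200), and the factor gene HSFA2. The others were PMZ (AT3G28210), the glucosyltransferase gene UGT74E2 (AT1G05680), the cytochrome P450 genes CYP81D8 (AT4G37370) and CYP81D11 (AT3G28740), and the glutathione transferase gene GSTU25 (AT1G17180). UGT74E2 rose from 2.67 ± 0.07 to 9.79 ± 0.08 (SD, n = 3 each). In mock, 10 of these 12 genes had means under 3.79, the level below which probe sets were treated as low, so their folds are uncertain. With low values raised to 3.74, the log2 change of HSP17.6A was 8.05 in place of 9.07, that of UGT74E2 6.04 in place of 7.12, and that of HSP70 stayed at 7.05. Of all 181 named genes, 35 had such low mock means, and the folds of 14 moved by over 1.5 times when low values were raised, down to 43.2-fold for CYP81D11, 42.5-fold for HSFA2, 169-fold for HSP17.6II and, among genes named further on, to 138-fold for AT1G53540, 15.6-fold for GSTU4, 8.91-fold for BIP3, 3.66-fold for WRKY30, 3.38-fold for PBS3, 1.72-fold for CYP71A12 and 1.65-fold for LOX4.

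The 12 named genes with the largest decreases began with GSTF14 (AT1G49860), a glutathione transferase gene that fell by 3.52 on the log2 scale (SE 0.27). DCF (AT3G48720), which encodes an enzyme that attaches ferulate to cutin, fell by 3.06 (SE 0.13). GASA6 (AT1G74670), a gibberellin-regulated gene, fell from 10.89 ± 0.08 to 7.99 ± 0.15 (SD, n = 3 each). AGP30 (AT2G33790), AIR1 (AT4G12550), CYP87A2 (AT1G12740), the extensin gene EXT13 (AT5G35190), GulLO2 (AT2G46750) and XTH12 (AT5G57530) fell by 2.54 to 3.04. With low values raised, GSTF14 was lower by 2.73 and CYP87A2 by 1.77. The type-A response regulator gene ARR6 (AT5G62920) was lower by 2.59 (SE 0.66, adjusted p = 0.0091), with a mock SD of 1.57. Its call ended with a trended, robust prior (adjusted p = 0.054) and without variance moderation (adjusted p = 0.087), and it was lower by 1.79 without mock replicate 1 and by 3.36 without mock replicate 3.

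**Figure D2:**
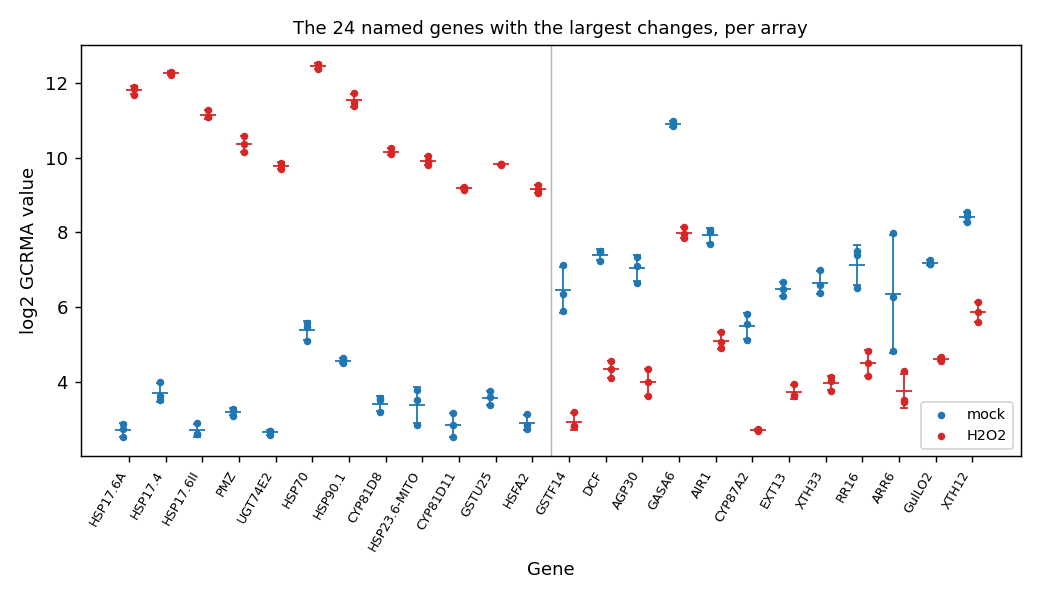
The log2 GCRMA values of the 24 named genes with the largest changes are shown per array, with 3 mock (blue) and 3 H2O2 (red) points per gene, the mean as a bar and the SD as whiskers. The 12 genes on the left were higher in every H2O2 array than in every mock array, and the 12 on the right lower.

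Heat shock proteins and factors rose as a group, with 33 of 36 measured genes higher, 1 lower and 2 not passing. Here and below, counts of list members cover only those that passed the filter on low values. This list had 41 members on the array, and the WRKY, salicylic acid, flavonoid and abscisic acid lists 58, 24, 23 and 19. The filter used the mean over both groups, so members low in mock could enter by rising. The share of members that rose can therefore be overstated. Besides the genes above, AT1G53540, a small heat shock protein gene, rose 324-fold (SE 0.11 log2). HSFC1 was lower by 0.75. The list was higher than other genes (camera adjusted p = 1.84e-22), and the call held with an estimated correlation (adjusted p = 0.031).

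All 19 measured genes of the xenobiotic and electrophile detoxification list rose, and 15 of them at least 2-fold. UGT73B4 (AT2G15490), a glucosyltransferase gene, rose 23.2-fold (SE 0.08 log2). The camera adjusted p was 4.44e-14, and 0.031 with an estimated correlation. Tau and phi glutathione transferases, which conjugate glutathione to toxic compounds, included 20 risers, 4 fallers and 4 that did not pass among 28. GSTU24 (AT1G17170) rose 47.0-fold (SE 0.12 log2) and GSTU4 (AT2G29460) 24.1-fold (SE 0.21 log2), whereas GSTF14 fell. Their camera adjusted p was 1.62e-08, a call lost with an estimated correlation (adjusted p = 0.14).

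Of 15 genes of the mitochondrial dysfunction response, 14 rose and 1 fell. The alternative oxidase gene AOX1A (AT3G22370) rose 22.8-fold (SE 0.11 log2), AT2G21640 53.6-fold (SE 0.09 log2) and the small heat shock protein gene AT5G51440 134-fold (SE 0.11 log2), while AOX1B was lower by 1.25. This list was called higher with the preset correlation (adjusted p = 4.01e-11) and with an estimated correlation (adjusted p = 0.031). Rapid reactive oxygen and wound response transcription factors rose in 16 of 18 cases. DREB2A (AT5G05410), a regulator of drought and heat responses, rose by 6.11 (SE 0.11), and the zinc finger genes RHL41 (AT5G59820), STZ (AT1G27730) and ZAT11 (AT2G37430) by 5.17, 3.89 and 3.84. Their adjusted p was 2.97e-11, and 0.031 with an estimated correlation.

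Genes for enzymes that remove reactive oxygen went both ways. Of 36 measured antioxidant enzyme genes, 5 rose, 21 fell and 10 did not pass, and the list was not called (camera adjusted p = 0.15). With each array centred on the reference genes, 7 rose and 13 fell. DHAR2 (AT1G75270), which regenerates ascorbate, rose 3.48-fold (SE 0.09 log2), GPX6 (AT4G11600) 2.83-fold (SE 0.09 log2) and the glutathione reductase gene GR1 (AT3G24170) 2.35-fold (SE 0.08 log2). The copper/zinc superoxide dismutase genes CSD2 (AT2G28190) and CSD1 (AT1G08830) were lower by 1.27 and 1.14 on the log2 scale, and CSD3 by 0.38. The changes of the catalase genes CAT1, CAT2 and CAT3 were -0.19, 0.03 and 0.19 on the log2 scale, with adjusted p of 0.082, 0.82 and 0.084. CAT3 passed with quantile normalization, with reference gene centring, with a trended, robust prior and without mock replicate 3 (0.26, adjusted p = 0.035), and CAT1 without mock replicate 2 (-0.25, adjusted p = 0.045). Among ascorbate peroxidases, APX1 rose by 0.64, APX6 and TAPX were lower by 0.56 and 0.43, and TL29 by 0.38. APX3 was lower by 0.19 (adjusted p = 0.046), a call lost in a paired model with the replicate number as a block (adjusted p = 0.054), without any one of the 6 arrays (0.062 to 0.15), without the filter, with quantile normalization and with reference gene centring. The changes of APX5, SAPX, MSD1 and FSD1 were 0.12, 0.01, -0.09 and -0.04 and did not pass, while FSD2 and FSD3 were lower by 0.30 and 0.36 (calls lost with reference gene centring, and that of FSD2 also without mock replicate 2, adjusted p = 0.064).

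Sulfate assimilation and glutathione synthesis genes rose in 19 of 26 cases and fell in 2. LSU2 (AT5G24660) and LSU1 (AT3G49580), which respond to sulfur limitation, rose 32.2-fold and 18.3-fold, and the APS reductase genes APR3 (AT4G21990) and APR1 (AT4G04610) 9.47-fold and 5.43-fold. The camera adjusted p was 7.42e-07, lost with an estimated correlation (adjusted p = 0.13). In the 26S proteasome list, 30 of 33 genes rose and 3 did not pass, with a median log2 change of 0.59. The transcription factor genes NAC053 (AT3G10500) and NAC2 (AT5G04410) rose 4.24-fold and 2.58-fold, and the proteasome subunit genes RPT5B (AT1G09100) and RPT3 (AT5G58290) 2.79-fold and 2.73-fold. The list had an adjusted p of 3.69e-12, and 0.12 with an estimated correlation. The unfolded protein response list had 9 risers and 1 faller among 17, among them ATERDJ3A (AT3G08970) at 22.6-fold, BIP3 (AT1G09080), an endoplasmic reticulum chaperone gene, at 18.1-fold, BZIP60 (AT1G42990) at 4.92-fold and SARA1A (AT1G09180) at 2.52-fold. Its adjusted p was 0.000247, and 0.16 with an estimated correlation. Autophagy genes rose in 7 of 20 cases and fell in 1, with ATG8H (AT3G06420) and ATG8B (AT4G04620) 2.84-fold and 2.23-fold higher, and NBR1 and APG8A up by 0.93 and 0.69 on the log2 scale. Their median change was 0.05 and the adjusted p was 0.046, with 0.23 under an estimated correlation, and the call ended without mock replicate 2 (0.060) or 3 (0.053) or H2O2 replicate 3 (0.061) and with array weights (0.058).

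WRKY transcription factor genes, many of which act in defence, rose in 25 of 40 cases, fell in 8 and did not pass in 7. WRKY30 (AT5G24110), WRKY33 (AT2G38470), WRKY70 (AT3G56400) and WRKY48 (AT5G49520) rose 7.17-fold to 10.2-fold. The WRKY list had an adjusted p of 4.38e-05, and 0.060 with an estimated correlation. In the salicylic acid list, 13 of 18 genes rose and 4 fell. GRX480 (AT1G28480), AIG1 (AT1G33960) and PBS3 (AT5G13320), which acts in salicylic acid synthesis, rose 13.1-fold, 6.84-fold and 6.75-fold. The pathogenesis-related genes PR1, PR5 and BGL2, commonly used as markers of the salicylic acid response, were lower by 1.94, 1.07 and 0.74, and were singled out after their values were seen. For the whole list the adjusted p was 0.000188, and 0.16 with an estimated correlation.

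Jasmonate genes rose in 11 of 17 cases and fell in 2, with LOX4 (AT1G72520), JAZ1 (AT1G19180), JAZ10 (AT5G13220) and LOX3 (AT1G17420) 2.12-fold to 2.50-fold higher, an adjusted p of 0.00114, and 0.38 with an estimated correlation. Ethylene genes were not called (adjusted p = 0.068; 5 rose, 3 fell, 9 did not pass, and 8 rose with reference gene centring), although ACS7 (AT4G26200), ACS6 (AT4G11280) and ACS2 (AT1G01480), which make the ethylene precursor, rose 14.8-fold, 10.1-fold and 4.62-fold, and PDF1.2 (AT5G44420) rose by 3.46 on the log2 scale. The ethylene list passed with quantile normalization (adjusted p = 0.035), without mock replicate 3 (0.039) and without H2O2 replicate 1 (0.029). Camalexin and indole glucosinolate genes rose in 13 of 14 cases, with PAD3 (AT3G26830), the last enzyme of camalexin synthesis, up 6.97-fold, CYP81F2 (AT5G57220) 4.01-fold, CYP71A12 (AT2G30750) 2.65-fold and CYP83B1 (AT4G31500) 2.37-fold. Their adjusted p was 9.05e-07, and 0.14 with an estimated correlation. Aliphatic glucosinolate genes rose in 9 of 17 cases and fell in 1, none by 2-fold, with FMO GS-OX3, CYP83A1, SOT17 and IPMI1 up by 0.50 to 0.75 on the log2 scale. The adjusted p was 0.00537, and 0.44 with an estimated correlation.

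Abscisic acid genes rose in 8 of 11 cases and fell in 1, with LEA4-5 (AT5G06760) up 3.91-fold and the phosphatase genes ABI2 (AT5G57050) and HAI1 (AT5G59220) 3.38-fold and 2.49-fold, and LTI78 1.83-fold. Their adjusted p was 0.0034, and 0.13 with an estimated correlation. Senescence and chlorophyll breakdown genes rose in 11 of 24 cases and fell in 4. RNS1 (AT2G02990), a ribonuclease gene, rose by 5.28 on the log2 scale, SAG13 (AT2G29350) 8.19-fold, DIN2 (AT3G60140) 5.34-fold and WRKY6 (AT1G62300) 4.98-fold. The adjusted p was 0.00928, 0.16 with an estimated correlation and 0.12 with the stricter filter on low values. Flavonoid and anthocyanin genes rose in 7 of 13 cases and fell in 1, led by PAL1 (AT2G37040) and C4H (AT2G30490), which open the general phenylpropanoid pathway, up by 2.07 and 1.61 on the log2 scale, with UGT78D2 and PAL2 both up by 0.77. This list had an adjusted p of 0.00997, and 0.43 with an estimated correlation.

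Photosynthetic light harvesting and electron transport genes fell in 33 of 40 cases, rose in 1 and did not pass in 6, with a median log2 change of -0.35. ATPD (AT4G09650), a chloroplast ATP synthase gene, fell 2.09-fold, PETE1 (AT1G76100), a plastocyanin gene, 1.94-fold and PSBO2 (AT3G50820) 1.74-fold. The riser was PSAT (AT4G35630), at 2.66-fold, which the list took in by its symbol but which is known to encode a phosphoserine aminotransferase. The list had an adjusted p of 7.04e-05, and 0.43 with an estimated correlation, and 19 members fell with reference gene centring and 20 with quantile normalization. Calvin cycle and photorespiration genes fell in 16 of 19 cases, among them PRK (AT1G32060) by 0.78, CP12-2 by 0.73, FBA1 by 0.70 and HCEF1 by 0.62, and adjusted over the list alone the count was 17. Their adjusted p was 0.00114, and 0.41 with an estimated correlation. Chlorophyll biosynthesis genes fell in 18 of 20 cases, among them the magnesium chelatase genes CHLI2 (AT5G45930) by 0.86 and CHLI1 by 0.70, HEME2 by 0.83 and CHLM by 0.74. This group had an adjusted p of 0.00014, and 0.30 with an estimated correlation.

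Expansin and xyloglucan endotransglucosylase genes, which act in cell wall loosening, fell in 26 of 40 cases and rose in 6, and 17 of the fallers fell at least 2-fold. EXPA1 (AT1G69530) and EXPA11 (AT1G20190) were 5.58-fold and 5.16-fold lower. The adjusted p was 0.000227, and 0.14 with an estimated correlation. DNA damage response genes rose in 11 of 17 cases and fell in 3. AT1G07500 rose 9.27-fold, PARP2 (AT4G02390) 3.35-fold and XRI1 (AT5G48720) 2.83-fold. The list had an adjusted p of 0.000331, and 0.16 with an estimated correlation.

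**Figure D3:**
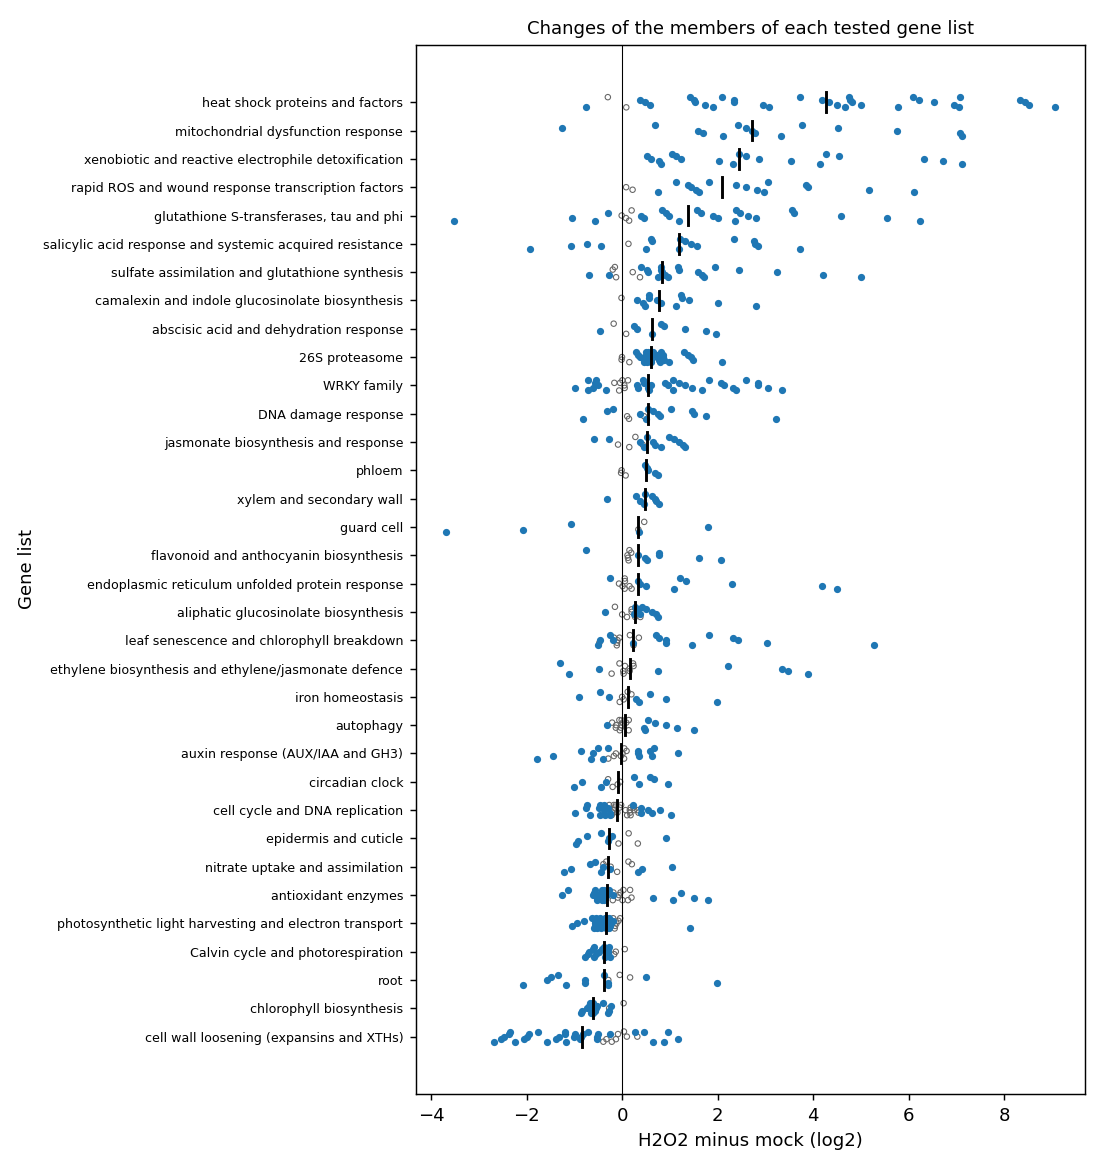
Each row is a tested gene list, ordered by median, and each point a member's difference H2O2 minus mock (log2, horizontal axis). Filled points passed an adjusted p of 0.05, open points did not, and black bars are list medians, from -0.85 for cell wall loosening to 4.26 for heat shock proteins and factors.

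Cell cycle genes did not move together (7 rose, 13 fell and 20 did not pass among 40, adjusted p = 0.90; 9 rose and 8 fell with reference gene centring), with TSO2 (AT3G27060) up by 1.03, CYCB1;1 (AT4G37490) up by 0.80, and CDC6 and MCM10 lower by 1.00 and 0.76. Auxin response genes (7 rose, 8 fell, adjusted p = 0.98; 4 rose without mock replicate 2, and 4 rose and 5 fell without variance moderation) included SAUR15 (AT4G38850) and IAA1 (AT4G14560), 3.44-fold and 2.72-fold lower, IAA29, lower by 0.86 (adjusted p = 0.065 without variance moderation), and GH3.3 (AT2G23170), 2.24-fold higher. Iron homeostasis genes (5 rose, 3 fell, adjusted p = 0.27; 3 rose without mock replicate 3, without H2O2 replicate 2 and without variance moderation) included NAS2, NAS1 and FER1, up by 1.98, 0.91 and 0.58, and FRO3, lower by 0.90. Clock genes (5 rose, 4 fell, adjusted p = 0.98; 2 rose without H2O2 replicate 1 and without variance moderation) included RVE1 and LHY, up by 0.96 and 0.67, and PRR3 and PRR5, lower by 1.02 and 0.85. The LHY call ended without H2O2 replicate 1 (0.54, adjusted p = 0.062) and without variance moderation (adjusted p = 0.10). Nitrate genes (3 rose, 7 fell, adjusted p = 0.33) included ASN2, LBD38 and FNR2, lower by 1.23, 1.07 and 0.67, and NRT2:1, up by 1.03. FNR2 is known as a leaf ferredoxin reductase of photosynthesis. The medians of the cell cycle, auxin and clock lists were -0.12, -0.03 and -0.10, and 0.01, 0.10 and 0.03 with reference gene centring, and the clock list's test pointed up while its median was below 0.

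Markers of other organs and cell types were measured beside these groups. Root genes fell in 10 of 15 cases and rose in 2, with PRP3 (AT3G62680), EXPA7 (AT1G12560) and the aquaporin gene TIP2;3 (AT5G47450) lower by 2.08, 1.57 and 1.49 and GPAT5 (AT3G11430), a suberin gene, up by 1.99. The root list's adjusted p was 0.045, and 0.43 with an estimated correlation. The root call was lost with the replicate block (adjusted p = 0.057), without mock replicate 1 (0.054), without H2O2 replicate 2 (0.086), with array weights (0.060) and with the stricter filter (0.079). Phloem markers rose in 5 of 8 cases (SUC2 by 0.74, PP2-A1 by 0.68, APL by 0.54 but not passing without variance moderation, SULTR2;1 by 0.52) with an adjusted p of 0.024, and 0.30 with an estimated correlation. Xylem markers rose in 8 of 9 cases (IRX12 by 0.76, XCP2 by 0.71, XCP1 by 0.70, LAC17 by 0.62) with an adjusted p of 0.00407, and 0.13 with an estimated correlation. Guard cell markers (2 rose, 3 fell, 2 did not pass, adjusted p = 0.86; 4 rose with the replicate block) included AT1G22690, MYB60 and FMA, lower by 3.68, 2.07 and 1.08, and KAT1, up by 1.80, and their median was 0.34 while their mean was -0.56. Over the alternatives that median ran from -0.19 to 0.46. Epidermis and cuticle markers (1 rose, 7 fell, adjusted p = 0.24; 2 rose and 4 fell with reference gene centring) included KCS6, KCS10 and CER3, lower by 0.98, 0.93 and 0.74, and CER1, up by 0.91. Fewer than 5 members passed the filter on low values in the class III peroxidases, seed storage and shoot meristem lists, which were tested only without the filter and not called there. Among their members, PRX52 (AT5G05340) rose 14.6-fold, AT5G64120 was up by 0.39, Prx37 and PER64 were lower by 0.50 and 0.46, KNAT1 and ANT were up by 0.77 and 0.59, STM by 0.33 (adjusted p = 0.047, and 0.058 with the replicate block), and OLEO4 was at 0.22 (adjusted p = 0.060). Several of these calls were weak. The AT5G64120 call ended without mock replicate 2 (0.36, adjusted p = 0.063), without mock replicate 3 (0.36, 0.058) and without variance moderation (0.081), and that of Prx37 without variance moderation (0.076). The ANT call ended without H2O2 replicate 1 (0.53, 0.083), without H2O2 replicate 2 (0.55, 0.078) and without variance moderation (0.13). STM kept its call without mock replicate 1 and lost it without each of the 5 other arrays (0.20 to 0.38, adjusted p 0.057 to 0.14), while OLEO4 passed without H2O2 replicate 3 (0.28, 0.032), with array weights and with reference gene centring.

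Where few members of a list went against it, they were named after their values were seen. Such small counts were unsteady: the 4 fallers of the senescence list and the 3 of the DNA damage list were 1 each with reference gene centring and without H2O2 replicate 2, and the single fallers of the abscisic acid, unfolded protein, autophagy and xylem lists did not pass with that centring. Lower members of lists called higher were HSFC1, AOX1B, GSTF14, GSTU26, GSTU18 and GSTU28, PR1, PR5, BGL2 and DMR6, LOX2 and AOC4 of the jasmonate list, IMS2 of the aliphatic glucosinolate list, APS4 and OASB of the sulfate list, and PDIL1-1 and ATG8C. The others were RD26 of the abscisic acid list, DIN10, NOL, NYC1 and ACD1 of the senescence list, TT7 of the flavonoid list, BARD1, WEE1 and KU80 of the DNA damage list, and TED4 of the xylem list, which is known as a heme oxygenase. LCR67, ACO1 and ERS1 were lower in the ethylene list, SHR was higher beside GPAT5 in the root list, and ATMDAR2 was higher beside DHAR2, GPX6, GR1 and APX1 among the antioxidant genes.

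In all, 25 of 34 lists were called, 20 higher and 5 lower. Of these calls, 4 held with an estimated correlation: heat shock, detoxification, mitochondrial dysfunction and rapid response factors. Correlation within a list does not account for every lost call. The estimates for the WRKY, abscisic acid and xylem lists were 0.0045, -0.0014 and -0.016, below the preset 0.01. Their adjusted p still rose to 0.060, 0.13 and 0.13. A call lost under this alternative thus does not by itself show that a list's genes vary together. With arrays mixed between the groups, camera at the preset correlation still called 16 to 20 lists, since such mixtures carry part of the same difference. Adjusted over the list alone, the counts of changed members differed for 7 lists from those given over all probe sets tested. Among the reference genes, TUB6, ACT8, ACT2 and PP2AA3 were lower by 0.59, 0.47, 0.26 and 0.22, GAPC1 and UBQ10 were up by 0.43 and 0.40, and AT2G28390 and AT4G34270 were at -0.15 and -0.14 and did not pass. The ACT2 and PP2AA3 calls were lost with quantile normalization, with reference gene centring and without mock replicate 1 (ACT2 -0.24, adjusted p = 0.0503; PP2AA3 -0.22, 0.068). PP2AA3 was also lost without mock replicate 3 (-0.19, 0.096) and without H2O2 replicate 1 (-0.24, 0.052), 2 (-0.20, 0.071) or 3 (-0.23, 0.0502), and AT2G28390 passed without variance moderation (0.036).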

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

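The alternatives chosen after the data were seen were the lists without misplaced members and identical loci counted once. Changed probe sets stayed within 1.5 times 9066 under every alternative run (7054 to 9637, and 7930 to 8692 without 1 array), and the replicate block gave 9424. At least 2-fold changes were 1172 with the filter at the 50th percentile, where fewer probe sets were tested, and 1701 to 1815 without 1 array. The share higher among all changes was 40.6% without the filter, 37.3% with the stricter filter, 39.5% with quantile normalization, 40.0% with median centring, 55.0% (reversed) with reference gene centring, and 39.0% to 41.5% without 1 array; among changes of at least 2-fold it was 74.9% with reference gene centring. The cause was not tested beyond the scaling itself. The lists called numbered 4 with an estimated correlation, against 25, and 22 to 26 with camera otherwise. The choices of prior and of variance moderation do not enter camera here. The 25 calls under each of these 2 alternatives were thus fixed in advance and are no support. With fry, which does not compare a list with other genes, 30 passed, the 5 added being the antioxidant, ethylene, nitrate, guard cell and epidermis lists. Without misplaced members 25 lists were called. The paired fit with the replicate block ended the calls of the root list, APX3 and STM and changed no other call among the 34 lists and named genes, while ARR7, ARR9 and the histone list, chosen later, passed with it. Of 181 named genes, 164 kept call and direction under every alternative that tested them, and none reversed. The first component held 88.9% without the filter. Of the 10 splits of the 6 arrays, too few for a share under 0.05, 1 gave as many changed probe sets (9066, highest other 0), as many changed at least 2-fold (1766, highest other 0) and as many called lists (25, highest other 20). The other 3 splits that part all 3 same-numbered pairs called 16 to 20 lists. In limma they called 0 probe sets, with 41 to 51 at an unadjusted p under 0.05 against 9687 for the real split. Each mixed split still carries part of the treatment difference, and its changes correlated with the real ones at 0.890 to 0.938 in size. The rest of that difference lies within its groups and widens their spread. Low limma counts were thus fixed in advance for mixed splits and do not measure false calls. Signal near background limits genes whose mock level was low. Over the alternatives, adjusted p ran from 0.00075 to 0.087 for ARR6, 0.015 to 0.52 for APX3, 0.01 to 0.14 for STM, 0.015 to 0.26 for CAT3 and, with camera alone, 0.0086 to 0.43 for the root list, 0.022 to 0.23 for the autophagy list, 0.029 to 0.43 for the ethylene list and 0.0025 to 0.16 for the senescence list.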

Other observations

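All lists in this part were chosen after the data were seen, and their camera p-values were adjusted over these lists alone. The root hair list holds XTH12, EXT13, PRP3 and EXPA7, and the type-A response regulator list RR16 and ARR6, whose falls had already been seen. Camera and permutation p-values of these lists are therefore no independent support. The tests of root hair genes and of replicate numbers were written after their results. Those of the floor, of the majority and of splits were written before. Type-A response regulator genes, which damp cytokinin signalling, fell in 6 of 8 measured cases. RR5 (AT3G48100) was lower by 2.05 (SE 0.30) and RR3 (AT2G41310) by 1.71 (SE 0.08), while ARR7 and ARR9 were at -1.02 and -0.48 and did not pass (adjusted p = 0.076 and 0.12). Both passed with the replicate block (0.0085 and 0.025) and without mock replicate 3 (-1.51 and -0.73, adjusted p = 0.0067 and 0.014). Genes of suberin synthesis and transport rose in 11 of 13 cases and fell in 1, with the transporter gene ABCG6 up by 3.59, RWP1 (AT5G41040) by 2.55 and CYP86B1 by 2.15, whereas KCS20 was lower by 0.45. The mock means of ABCG6 (2.73), CYP86B1 (3.04), ABCG16 (3.04), FAR4 (3.13), ABCG20 (3.23), GPAT5 (3.39) and FAR5 (3.69) were under 3.79, so their folds are uncertain. These genes passed the filter on low values only through their H2O2 values. The count of suberin risers and the camera result therefore partly reflect the filter. The risers CYP86A1, KCS2, FAR1 and RWP1 had mock means above 3.79. Camera adjusted p was 0.00533 for the regulators and 5.91e-05 for suberin, and 0.54 for both with an estimated correlation. Ribosomal protein genes fell in 24 of 37 cases and rose in 2 (median -0.36, adjusted p = 0.00313, and 0.54 with an estimated correlation), and with reference gene centring 16 fell and 4 rose. Histone genes fell in 10 of 17 cases and rose in 1 (adjusted p = 0.11, 0.041 with the replicate block and 0.015 without mock replicate 3), and 5 fell with reference gene centring and 4 without variance moderation.

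Root hair genes fell in all 16 measured cases, by 0.78 to 2.74 on the log2 scale (median -1.93, camera adjusted p = 1.75e-08, and 0.54 with an estimated correlation), although the labels name leaf as the tissue (and seedling as the source). A smaller share of root tissue in the H2O2 pools would lower other root markers alike. The 7 other root markers had a median of -0.29, above the root hair median by 1.64 (permutation p = 0.00049, two-sided, genes not being independent), and the abundant root gene PYK10 was at -0.05. These 7 leave out 4 other members of the planned root list, of which TIP2;3, PIP2;4 and MYB66 were at -1.49, -1.35 and -0.79 and GPAT5 at 1.99. With these added the median of the 11 was -0.30, above the root hair median by 1.63 (permutation p = 7.0e-05). Both permutation p-values use a list chosen after its falls were seen, so they are no support. The small median change of these 11 planned markers argues against a smaller share of root tissue as the whole cause. TIP2;3, PIP2;4 and MYB66 fell within the range of the root hair genes, which leaves open a part in the lower values. Reference gene centring adds the same 0.12 to the change of every gene, so the median of -1.81 with it is no separate test. The shift itself was small beside falls of 0.78 to 2.74, which argues against an offset between arrays as the whole cause. An effect of H2O2 on root hair cells, or fewer of these cells in the pools, may remain as explanations and were not tested.

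The majority of all changes was downward and that of changes of at least 2-fold upward. Among 682 probe sets with a mean of at least 7 that changed at least 2-fold, 63.5% were higher (exact 95% interval 59.8% to 67.1%, probe sets not being independent). That mean was taken over both groups, so genes low in mock could enter by rising, such as HSP17.6A (2.73 in mock, log2 change 9.07). The test therefore cannot decide whether a floor hid decreases, and this is left open. An offset between arrays could account for the downward majority, since it turned to 55.0% higher with reference gene centring, but the downward majority stayed with quantile normalization (39.5% higher) and with median centring (40.0% higher). Those 8 genes themselves moved by -0.59 to 0.43, so which scaling is right stays open, as does an effect of H2O2, which was not tested apart from it.

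Genes of the hypoxia core response rose in 13 of 22 cases (8 without variance moderation), fell in 1 and did not pass in 8. Risers included ERF71 (4.34) and PDC2 (1.47), and the faller was ERF73 (-1.25). ADH1 (-0.33), SUS4 (-0.62) and FTM1 (0.09) were among those that did not pass. The list had a median of 1.24 and a camera adjusted p of 0.000671, and 0.54 with an estimated correlation. Replicates of the hypoxia genes were spread widely. Their median SD was 0.54 over mock arrays and 0.67 over H2O2 arrays, against 0.09 and 0.11 for all tested probe sets. Deviations of same-numbered arrays correlated at 0.39 to 0.70 across these genes, and 1 of the 6 ways to match mock with H2O2 arrays gave as high a mean (0.56, against 0.29 for the next). Their overall level was not shared by number 1, where the median deviations were 0.16 in mock and -0.58 in H2O2; those of number 2 were -0.33 and -0.03, and those of number 3 were 0.22 and 0.65. A growth or harvest batch shared by number may account for the correlations, but 6 matchings are too few to decide.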
